A study of Mus musculus with 12 samples.

How the data were processed

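RNA from the striatum of mice was sequenced at 7 and 14 days after ischemic stroke, in WT mice and in mice labelled cGAS-KO or STING-KO, with 2 libraries per group and 12 in all. Per the labels, both lines were made with CRISPR-Cas9 on a C57BL/6J background, RNA was extracted with Trizol, and polyA+ libraries were sequenced with paired reads on an Illumina HiSeq 2500. The deposited values are raw counts per Ensembl gene ID, 1 column per library. Per the submitters' processing notes, the reads were aligned to mm10 with HISAT2 and the counts made with featureCounts; their versions, the annotation release and the strand setting are not given there. Whether reads were counted by strand was not settled, so antisense and overlapping genes cannot be told apart in these values. The counts were whole numbers, with totals of 15956242 to 22126213 per library.

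Symbols and coordinates come from GENCODE M21, whose assembly GRCm38 is mm10; 54409 of the 54532 IDs had a symbol. STING is named Tmem173 there. CPM were computed with edgeR from the counts and the library total multiplied by its TMM factor. Floors for a count of 0 use 3 counts per library, and these floors cover counting error only.

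Genes were tested with edgeR 4.0.16 in R 4.3.3 on the raw counts. filterByExpr (minimum count 10, minimum total 15) with the 6 groups kept 19822 genes, TMM factors were used, and all 12 libraries entered 1 fit with 1 factor of 6 groups, which left 6 residual degrees of freedom. Dispersion was estimated with estimateDisp (robust; biological coefficient of variation 0.194), the quasi-likelihood fit used glmQLFit with robust estimation, and p-values of glmQLFTest were Benjamini-Hochberg adjusted over the genes of 1 contrast, with a threshold of 0.05 and no fold minimum. SE is the absolute log2 change over the square root of F. The design fixed in advance did not name the legacy setting of glmQLFit, whose installed default is the legacy form. Both forms had been computed, the legacy one first. The newer form was kept because the alternative fixed in advance was the legacy one; the closing section gives the counts of both.

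The contrasts were each labelled knockout against WT at each time and over both times, the labelled knockouts against each other over both times, 14 against 7 days within each genotype, and the difference of each knockout effect between the times. These 12 were chosen before the data were examined, as were the alternatives, the gene lists and the rule for named genes. The knockouts against each other at 7 and at 14 days were 2 contrasts added after the data had been seen. Gene lists, 46 in all for cell types, pathways and RNA quality, were tested with camera (limma 3.58.1; preset correlation 0.01), with camera using an estimated correlation and with fry, adjusted over the lists of 1 contrast. Effects were compared across genes by Pearson's r, Spearman's rho, covariance and overlap of calls; comparisons that share WT libraries were set beside 20 simulations of unchanged groups against the same controls.

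The text names the targeted genes, genes among the 8 largest rises and 8 largest falls of each knockout comparison (adjusted p below 0.05, logCPM of at least 1, libraries of both groups fully separated), up to 4 members per list with the smallest adjusted p (or, with none called, the 2 with the smallest p as values), and the 6 largest rises and falls between times. The same form of rule was applied to the contrasts added later. Exceptions are named where they occur.

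The test was tried on simulated counts with known changes, drawn from the means and library sizes of the real data. The changed genes were picked only among those averaging at least 1 CPM, so recovery of genes below that was not tried. For cGAS-KO against WT at 14 days, over 19822 genes, it recovered 41% of 100 genes changed 2-fold and 88% of 100 genes changed 4-fold, and 15 of 144 calls were false, more than the 5% aimed at. For cGAS-KO against WT over both times it recovered 61% and 92%, with 7 false calls of 160. Calls near the threshold are to be read with that excess in mind.

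Alternatives were DESeq2's size factors in edgeR, the DESeq2 1.42.0 Wald test, no filter, a stricter filter (1 CPM and 10 counts in 2 libraries), only the libraries compared, the replicate number as a block, the legacy quasi-likelihood fit without robust estimation, and leaving out each library in turn. The legacy fit with robust estimation, and a fit without the 7-day WT and 14-day STING-KO groups, were added after the data had been seen. When a library was left out, the lone library of its group was taken to vary like the other groups. Figures were drawn with matplotlib 3.10.9 in python 3.11.15.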

Results

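RNA sequencing of the mouse striatum at 7 and 14 days after ischemic stroke compared wild-type (WT) mice with mice labelled as knockouts of Cgas (cGAS-KO) or of Tmem173, the gene of STING (STING-KO). cGAS is an enzyme that senses cytosolic DNA, and STING is the adaptor that its product, the cyclic dinucleotide cGAMP, activates to induce type I interferons and inflammatory cytokines. The 6 groups of time and genotype held 2 libraries each, 12 in all, with no uninjured group. Library totals ran from 15956242 counts (14-day STING-KO, replicate 2) to 22126213 counts (14-day cGAS-KO, replicate 1), and 23492 to 25861 genes per library had a count. At this depth, 3 counts equal 0.133 to 0.195 CPM, the count scaled to the normalised library total. Of 54532 annotated genes, 19822 were tested. Group values are mean CPM ± SD with n = 2, and differences are log2 changes ± SE from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Its p-values measure the spread between these libraries, since the labels do not say whether libraries came from separate mice.

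The targeted transcripts did not follow the labels in every comparison. Cgas (ENSMUSG00000032344; mm10, chromosome 9, 78430526 to 78443237, minus strand) averaged 3.11 ± 0.20 CPM in the 7-day WT libraries and 5.60 ± 0.077 CPM in the 7-day libraries labelled cGAS-KO. That rise of 0.85 ± 0.32 passed the threshold narrowly (adjusted p = 0.0438), and it no longer did when any 1 of the 4 libraries was left out, with adjusted p from 0.118 to 0.183, or under 4 of 8 other settings, with 0.069 at most. At 14 days Cgas averaged 10.1 ± 3.45 CPM in the WT libraries and 5.12 ± 1.45 CPM in those labelled cGAS-KO. That difference was -0.98 ± 0.28 (edgeR adjusted p = 0.27, unadjusted p = 0.00494). At 7 days Cgas also stood lower in the libraries labelled cGAS-KO than in those labelled STING-KO (-1.09 ± 0.28, adjusted p = 0.181, unadjusted p = 0.00253). These 2 comparisons share no library. Neither passed over all genes, but Cgas was named in advance, so the adjustment over all genes is strict for it. Against STING-KO at 14 days Cgas was not lower in cGAS-KO (0.33 ± 0.31, unadjusted p = 0.307). In the libraries labelled STING-KO it averaged 11.9 ± 1.0 CPM at 7 days and 4.04 ± 0.65 CPM at 14 days. Tmem173 (ENSMUSG00000024349; chromosome 18, 35733679 to 35740554, minus strand) was lowest in the 7-day WT libraries, at 2.80 and 2.71 CPM, and in the 14-day libraries labelled STING-KO, at 2.40 and 5.21 CPM. In the 7-day libraries labelled STING-KO it stood at 20.9 and 23.8 CPM, near the 14-day WT libraries at 22.3 and 20.8 CPM and below the 7-day libraries labelled cGAS-KO at 28.7 and 30.3 CPM. Against WT, Tmem173 was therefore higher by 3.02 ± 0.28 at 7 days (adjusted p = 4.2e-06) and lower by 2.51 on the same scale at 14 days (log2 change -2.51 ± 0.27, adjusted p = 8.19e-05) in the libraries labelled STING-KO. Gene-level counts cannot show a small CRISPR-Cas9 deletion or insertion that leaves the transcript in place. The genotype names are therefore used as labels throughout, and every direction given between genotypes is a direction between libraries labelled so.

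**Figure D1:**
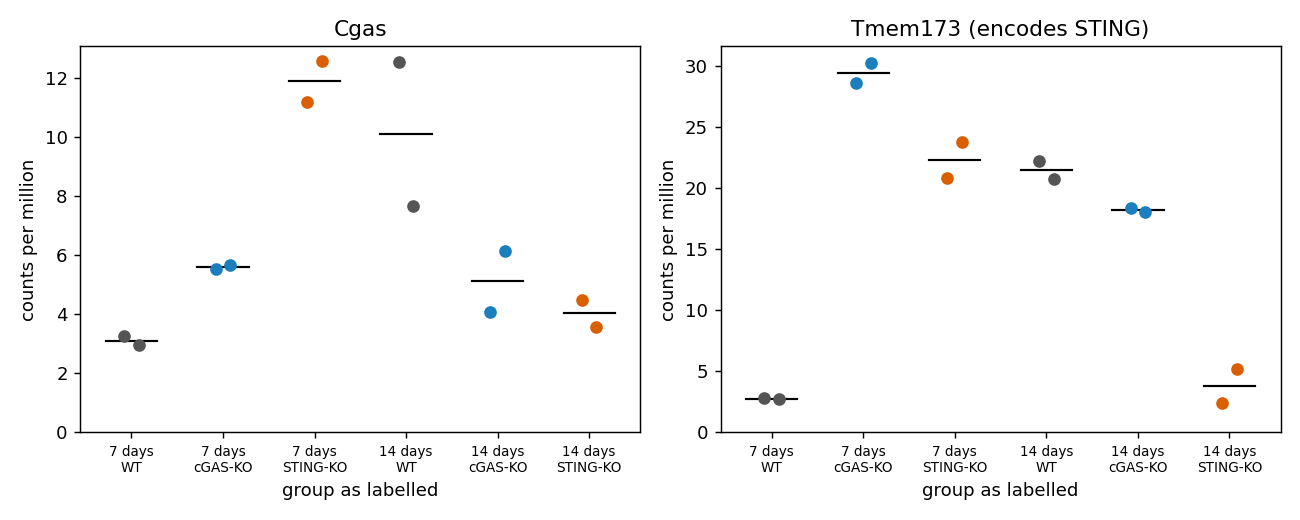
Cgas and Tmem173 in CPM (vertical axes) in each of the 6 groups as labelled; points are the 2 libraries of a group and bars their mean. Tmem173 lies at 2.71 to 2.80 CPM in the 7-day WT libraries and at 2.40 to 5.21 CPM in the 14-day libraries labelled STING-KO, and at 18.1 CPM or more in the other 8.

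The first principal component of log2 CPM held 50.9% of the variance and set the 7-day WT libraries (scores 89.3 and 103) and the 14-day libraries labelled STING-KO (118 and 90.0) against the 7-day libraries labelled cGAS-KO (-111 and -88.1) and STING-KO (-96.8 and -95.9). The 14-day WT (-16.5 and -4.14) and 14-day cGAS-KO libraries (10.7 and 1.49) lay between them. The second component, with 22.1%, set the 7-day WT libraries (94.1 and 103) apart. Marker genes of neurons, chosen here after their values were seen, differed along these components. Drd1, the dopamine receptor of striatal projection neurons, had 4.77 and 4.45 CPM in the 7-day WT libraries, 42.0 and 33.9 CPM in the 14-day WT libraries, and 376 and 325 CPM in the 14-day libraries labelled STING-KO. Slc17a7, the vesicular glutamate transporter of cortical and hippocampal neurons, reached 1272 and 1524 CPM in the 7-day WT libraries. Low striatal transcripts were not peculiar to the 7-day WT libraries. The striatal projection neuron list had a mean log2 CPM of 4.15 and 4.04 in them. It had 2.99 to 4.05 in the 7-day libraries of both labelled knockouts and 5.09 to 7.38 in the 14-day libraries. The list of neuronal and synaptic genes stood at 8.84 and 8.98 in the 7-day WT libraries and at 8.11 at most in all others. Every comparison with the 7-day WT libraries includes these differences in neuronal transcripts.

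**Figure D2:**
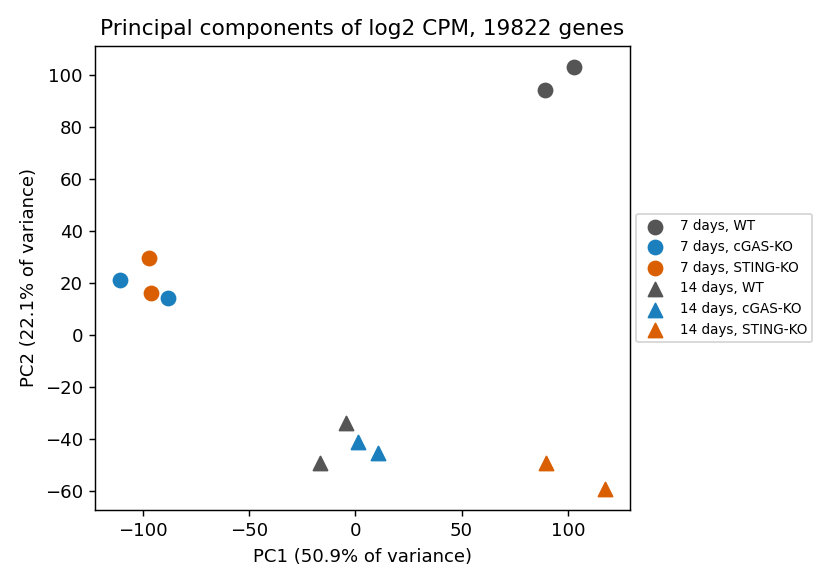
First (50.9% of the variance) and second (22.1%) principal components of log2 CPM; each point is a library, colours give the labelled genotype and shapes the day. The 7-day WT libraries lie at scores of 94.1 and 103 on the second component.

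Whether loss of cGAS or STING changes expression after stroke is the question of the series. At 7 days, 9964 genes differed between the libraries labelled cGAS-KO and WT, 5515 higher and 4449 lower in cGAS-KO. Lgals3, the galectin of phagocytes, averaged 1.08 CPM in WT and 371 CPM in cGAS-KO, higher by 8.45 ± 0.47 (adjusted p = 3.24e-07). Plin2, which coats lipid droplets, rose by 6.81 ± 0.33 (adjusted p = 1.48e-07), and the scavenger receptor Msr1 by 7.78 ± 0.33 (adjusted p = 1.19e-07). Bst2, an interferon-induced restriction factor, rose from 3.16 to 102 CPM (5.02 ± 0.46, adjusted p = 5.96e-06). The cell cycle genes Cdk1 (6.89 ± 0.41) and Mki67 (4.55 ± 0.25) and the collagen chaperone Serpinh1 (4.60 ± 0.22) were higher too. Atp6v0d2, a subunit of the lysosomal proton pump, averaged 22.2 ± 4.57 CPM in cGAS-KO and had 0 counts in WT (adjusted p = 1.77e-05). The AMPA receptor subunit Gria1 averaged 892 CPM in WT and 108 CPM in cGAS-KO, a change of -3.04 ± 0.22 (adjusted p = 8.43e-07). C1ql2, known from dentate granule cells, fell from 116 to 2.48 CPM (-5.59 ± 1.02, adjusted p = 0.000905), and Shox2, a thalamic transcription factor, from 27.0 to 0.335 CPM (-6.31 ± 0.46). The choroid plexus genes Tmem72 (5.51 ± 0.54) and Folr1 (4.79 ± 0.46) were higher in cGAS-KO. So were 24 of 25 genes of the choroid plexus list, also adjusted over the list alone (median 4.14, camera adjusted p = 0.24 with an estimated correlation). That list had a mean log2 CPM of 4.39 to 5.33 in the 7-day libraries of both labelled knockouts and 2.45 at most in all others. Whether choroid plexus tissue entered those samples was not tested.

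The gene lists moved with these genes. Among 67 interferon-stimulated genes, 64 were higher, 65 when adjusted over the list alone, with a median change of 2.95 (adjusted p = 0.316 with an estimated correlation). Of 32 disease-associated microglia genes, 30 were higher and 1 lower, with the same counts adjusted over the list alone and a median of 4.28 (adjusted p = 0.144 with an estimated correlation). The 33 genes of phagocytosis and lysosome were all higher, as they were adjusted over the list alone, with a median of 4.24 (adjusted p = 0.144 with an estimated correlation). Of 46 cell cycle genes, 43 were higher and 1 lower, the same adjusted over the list alone (median 3.90, adjusted p = 0.144 with an estimated correlation). Of 47 neuronal and synaptic genes, 46 were lower, also when adjusted over the list alone (median -2.10, adjusted p = 0.144 with an estimated correlation). Striatal projection neuron genes went both ways, with 5 of 48 higher and 17 lower, again the same adjusted over the list alone (median -0.47, adjusted p = 0.625 with an estimated correlation). The list of cytosolic ribosomal proteins, included for RNA quality, was also higher in 74 of 78 genes, 76 adjusted over the list alone (median 1.11, adjusted p = 0.337 with an estimated correlation), and its genes took 2.58% and 2.92% of the counts in cGAS-KO against 1.17% and 1.25% in WT. By camera with a preset correlation of 0.01, 34 of 46 lists passed, 27 up and 7 down. With an estimated correlation 0 passed after adjustment and 14 at an unadjusted p below 0.05, while fry called 39.

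In the 7-day libraries labelled STING-KO, 9694 genes differed from WT, 5218 higher and 4476 lower. The fatty acid transporter Cd36 was higher by 8.31 ± 0.42 (adjusted p = 1.54e-07), Plin2 by 7.44 ± 0.34 (adjusted p = 8.91e-08) and the matrix glycoprotein Thbs1 by 6.52 ± 0.35. Col10a1, a short-chain collagen, had 501 and 101 CPM in STING-KO against 0.168 and 0.051 CPM in WT (adjusted p = 1.18e-05). Bst2 averaged 111 CPM, higher by 5.14 ± 0.46 (adjusted p = 5.29e-06), and the ubiquitin ligase Trim25 rose by 2.55 ± 0.24 (adjusted p = 5.15e-06). Neurod6, a transcription factor of cortical and hippocampal pyramidal neurons, averaged 139 CPM in WT and 2.57 CPM in STING-KO (-5.75 ± 0.50, adjusted p = 4.79e-06). Of the interferon-stimulated genes 64 of 67 were higher, also adjusted over the list alone, with a median of 2.57 (adjusted p = 0.337 with an estimated correlation). Of the disease-associated microglia genes 31 of 32 were higher, also adjusted over the list alone (median 5.12, adjusted p = 0.153 with an estimated correlation). Of the cytosolic ribosomal protein genes 74 of 78 were higher, 75 adjusted over the list alone (median 1.22, adjusted p = 0.301 with an estimated correlation). All but 1 of the 47 neuronal and synaptic genes were lower, 47 adjusted over the list alone (median -1.98, adjusted p = 0.169 with an estimated correlation). Libraries of both groups separated fully for 80.9% of all genes tested here and for 80.2% in the cGAS-KO comparison, where 2 against 2 gives 33.3% by chance.

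Both knockout comparisons at 7 days share the WT libraries. Across genes, which are not independent replicates, their log2 changes correlated at r = 0.932, where simulated groups without effect against the same controls gave 0.493. The covariance was 2.73 against a simulated 0.157, a difference of 2.58. The simulated libraries varied independently around the WT mean. A deviation shared by both 7-day WT libraries, which stood apart, would raise r and the covariance without any shared effect of the knockouts. Higher in both were 4708 genes, against 1452 for independent lists, and lower in both 3819 against 1005; these expected numbers leave the shared WT libraries out of account. Set directly against each other, which leaves WT out, the 7-day libraries labelled cGAS-KO and STING-KO differed in 32 genes, 17 higher and 15 lower in cGAS-KO. This comparison and its 14-day counterpart were added after the data had been seen. Under 9 settings other than leaving out 1 library, the 7-day count ran from 2 (only the libraries compared) to 260 (DESeq2). Shox2 was lower in cGAS-KO by 5.42 on the log2 scale (-5.42 ± 0.48, adjusted p = 0.00242), as were the collagenase Mmp13 (-4.31 ± 0.47, adjusted p = 0.0033) and Rgs1, a regulator of chemokine signalling in leukocytes (-2.05 ± 0.21, adjusted p = 0.0033). The gap junction gene Gjb2 was higher (2.07 ± 0.23, adjusted p = 0.00645). The count depended on single libraries: it was 0 without cGAS-KO replicate 1, 202 without cGAS-KO replicate 2 and 8 without STING-KO replicate 1. Without cGAS-KO replicate 1 each of these 4 genes had an adjusted p of 0.0598, the highest over the libraries left out, and without STING-KO replicate 1 that of Gjb2 was 0.0555. Fitted with only the libraries compared, their adjusted p were 0.152 (Shox2), 0.185 (Mmp13), 0.0871 (Rgs1) and 0.148 (Gjb2), and Mmp13 also lost its call in both legacy fits (0.0566 and 0.0605). Markers of blood and of other cells were among the lists that moved. Of 7 erythrocyte genes 2 were higher in cGAS-KO, 6 adjusted over the list alone (median 3.34, adjusted p = 0.101 with an estimated correlation). Of 41 fibroblast and matrix genes 3 were higher, 18 higher and 1 lower adjusted over the list alone (median 0.99, adjusted p = 0.445 with an estimated correlation). Of 27 thalamic and hypothalamic neuron genes 3 were lower, 10 lower and 2 higher adjusted over the list alone (median -0.45, adjusted p = 0.101 with an estimated correlation). The interferon-stimulated genes had a median of 0.22 between these groups and the disease-associated microglia genes -0.47. By edgeR over all genes 0 members of either list passed, while at an unadjusted p below 0.05 2 of the former were higher and 7 of the latter lower in cGAS-KO.

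At 14 days, 6 genes differed between the libraries labelled cGAS-KO and WT, all lower in cGAS-KO. The myeloid lectin Clec4d (chromosome 6) fell by 4.38 ± 0.58 (adjusted p = 0.0114), and Slfn4, an interferon-induced gene of monocytes and neutrophils (chromosome 11), by 4.62 ± 0.58 (adjusted p = 0.0114). F13a1, the coagulation factor subunit of macrophages (chromosome 13), fell by 3.09 ± 0.36 (adjusted p = 0.0114), and Msr1 (chromosome 8) by 2.12 ± 0.24 (adjusted p = 0.0114). Thbs1 (chromosome 2) fell by 2.37 ± 0.30 (adjusted p = 0.0233). Mmp8, the neutrophil collagenase (chromosome 9), had 1.69 and 3.29 CPM in WT and 0 counts in cGAS-KO (adjusted p = 0.0136). These calls rested on single libraries. Over the libraries left out in turn, adjusted p of the 6 genes ran from 0.00135 to 0.111. Without cGAS-KO replicate 1 the count was 18 (15 higher, 3 lower) and each of the 6 lost its call, with adjusted p from 0.0536 (Mmp8) to 0.0932 (Thbs1). Without cGAS-KO replicate 2 it was 0, and the 6 lay between 0.0922 (F13a1) and 0.111 (Clec4d). Without WT replicate 1 it was 10, with Thbs1 at 0.11, and without WT replicate 2 F13a1 stood at 0.051 and Mmp8 at 0.0615. DESeq2 called 137 genes, 51 higher and 86 lower. At an unadjusted p below 0.05 in edgeR, 2185 genes differed, and the libraries separated fully for 40.9% of genes, where chance gives 33.3%. In simulated counts for this comparison, 41% of genes changed 2-fold and 88% of genes changed 4-fold were recovered, among genes averaging at least 1 CPM.

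Several genes at 14 days differed in value without passing the threshold. Spp1, the osteopontin gene of activated phagocytes, averaged 888 CPM in WT and 94.7 CPM in cGAS-KO (-3.23 ± 0.48, adjusted p = 0.0608). The interferon-induced Ifi27l2a stood at -2.0 ± 0.31 (adjusted p = 0.0614) and mt-Co3, a mitochondrial transcript whose reads a nuclear copy may share, at -2.47 ± 0.36 (adjusted p = 0.0566, with 0.00548 to 0.175 over the libraries left out, the lowest without cGAS-KO replicate 1). The retinoid receptor Rxrg of striatal neurons stood at 1.37 ± 0.22 (adjusted p = 0.0614). Spp1, Ifi27l2a and Rxrg passed under 3 of 9 other settings each and mt-Co3 under 2, DESeq2 among them for all 4. Of the 67 interferon-stimulated genes, edgeR called 0 over all genes, 49 lower at an unadjusted p below 0.05 and 39 lower adjusted over the list alone, with a median of -0.91 (adjusted p = 0.459 with an estimated correlation). Of 25 monocyte and macrophage genes 2 were lower, 15 adjusted over the list alone (median -1.89, adjusted p = 0.0517 with an estimated correlation). Of 8 neutrophil genes 1 was lower, 6 adjusted over the list alone (median -2.93, adjusted p = 0.0517 with an estimated correlation). Of 48 striatal projection neuron genes 25 were higher adjusted over the list alone, with no call over all genes (median 0.96, adjusted p = 0.442 with an estimated correlation). Camera called 28 of 46 lists with the preset correlation and 0 with an estimated one (4 at an unadjusted p below 0.05), and fry called 1, the monocytes and macrophages (adjusted p = 0.0467).

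Between STING-KO and WT at 14 days 6717 genes differed, 3265 higher and 3452 lower in the libraries labelled STING-KO. Spp1 fell by 6.43 ± 0.57 (adjusted p = 4.64e-05), Lgals3 by 3.91 ± 0.40 (adjusted p = 8.67e-05) and Fcer1g, the Fc receptor gamma chain, by 3.22 ± 0.24 (adjusted p = 1.96e-05). Among interferon-induced genes, Ifi27l2a fell by 4.71 ± 0.39 (adjusted p = 3.28e-05), Ifi207 by 4.51 ± 0.43 (adjusted p = 5.54e-05) and Ifit2 by 2.42 ± 0.27 (adjusted p = 9.79e-05). The immunoproteasome subunit Psmb8 fell by 3.30 ± 0.33, the complement component C3 by 4.13 ± 0.54 and Mbp, of myelin, by 1.95 ± 0.29. Genes of striatal neurons were higher. The sodium channel subunit Scn4b rose from 112 to 1219 CPM (3.45 ± 0.41, adjusted p = 0.000192), the serotonin receptor Htr1b by 3.39 ± 0.32 (adjusted p = 4.89e-05), Foxp2 by 2.32 ± 0.17 (adjusted p = 1.82e-05) and Rxrg from 22.8 to 131 CPM (2.53 ± 0.22). The neurotrophic factor Gdnf (2.94 ± 0.45, adjusted p = 0.000474) and the cholinergic enzyme Chat (2.81 ± 0.49, adjusted p = 0.00124) were higher too. The neuropeptide Cck of cortical neurons fell by 3.32 ± 0.41. Ifi207, Slfn4 and Ifi27l2a have near copies among their neighbours, and the counting may have divided reads between them.

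All 67 interferon-stimulated genes were lower in the 14-day libraries labelled STING-KO, also adjusted over the list alone, with a median of -2.89 (adjusted p = 0.163 with an estimated correlation). Of 29 T and NK cell genes 25 were lower and 1 higher, the same adjusted over the list alone (median -3.04, adjusted p = 0.313 with an estimated correlation). Of the disease-associated microglia genes 29 of 32 were lower, 30 adjusted over the list alone (median -2.53, adjusted p = 0.163 with an estimated correlation). Of 23 genes of MHC class I presentation 22 were lower, also adjusted over the list alone (median -2.24, adjusted p = 0.163 with an estimated correlation). Of the striatal projection neuron genes 41 of 48 were higher, 43 adjusted over the list alone (median 2.34, adjusted p = 0.163 with an estimated correlation). Of 33 cortical neuron genes 8 were higher and 18 lower, the same adjusted over the list alone (median -1.57, adjusted p = 0.372 with an estimated correlation). Of the lists for RNA quality, 26 of 78 cytosolic ribosomal protein genes were lower, also adjusted over the list alone (median -0.47, adjusted p = 0.557 with an estimated correlation), and took 1.54% and 1.18% of the counts in STING-KO against 2.11% and 1.67% in WT. Of 15 mitochondrial genome transcripts 3 were lower, 2 adjusted over the list alone (median -0.76, adjusted p = 0.406 with an estimated correlation). Without WT replicate 1 the count of genes fell to 4203, and the fall of Cgas in this comparison (-1.32 ± 0.30, adjusted p = 0.00603) lost its call (adjusted p = 0.0623, the highest over the libraries left out, with 0.00337 as the lowest). Libraries separated fully for 63.5% of genes.

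**Figure D3:**
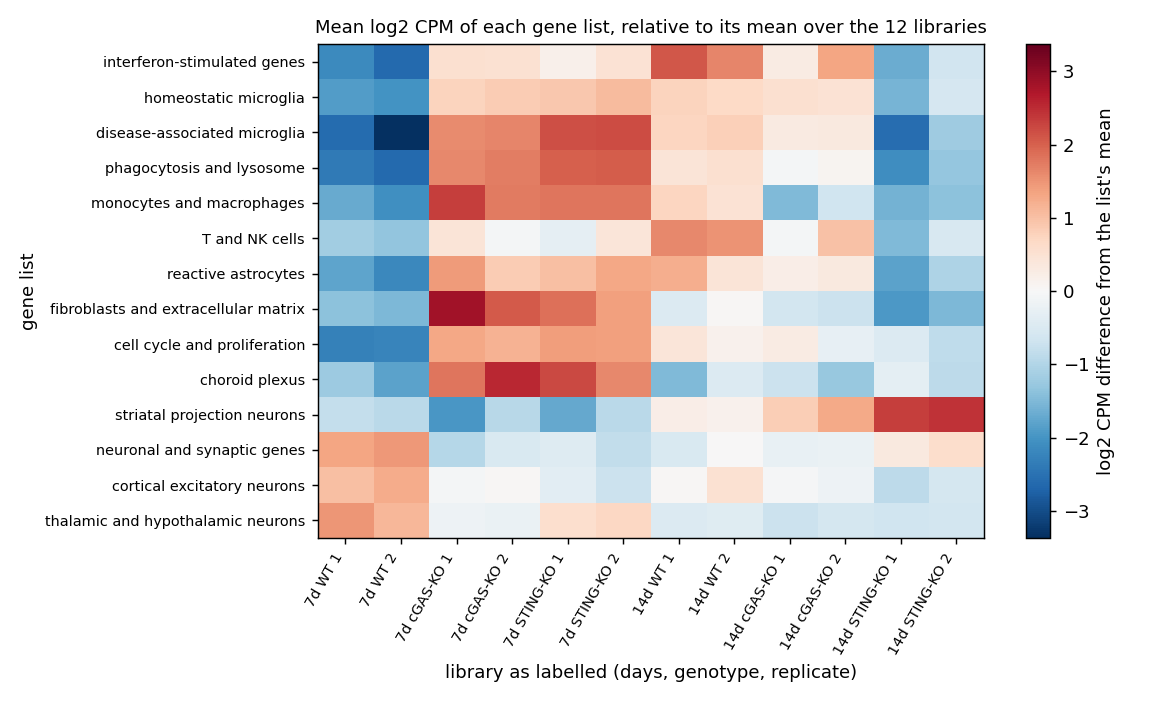
Mean log2 CPM of 14 gene lists (vertical) in each of the 12 libraries (horizontal), as the difference from the list's mean over all libraries. The immune lists are low and the general neuronal, cortical and thalamic lists high in the 7-day WT libraries, and the striatal projection neuron list is highest in the 14-day libraries labelled STING-KO.

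At 14 days the effects of the labelled knockouts correlated across genes at r = 0.433, where shared controls alone gave a simulated 0.502. It ran from 0.334 without cGAS-KO replicate 2 to 0.575 without WT replicate 2. The simulated value holds for 2 WT libraries and is no reference for a fit with 1. The covariance of 0.361 exceeded the simulated 0.135 by 0.226. This simulation too left out any deviation that both WT libraries share. The 6 genes lower in cGAS-KO were all lower in STING-KO as well. Since both comparisons use the same WT libraries, that overlap is no separate evidence; simulated groups without effect shared at most 1 gene called lower in both. Set directly against STING-KO at 14 days, the libraries labelled cGAS-KO differed in 7112 genes, 3612 higher and 3500 lower. The count was 4632 without cGAS-KO replicate 2 and 4728 without STING-KO replicate 1. Tmem173 was higher in cGAS-KO by 2.27 ± 0.27 (adjusted p = 0.0002). Of the 67 interferon-stimulated genes 61 were higher in cGAS-KO, 63 adjusted over the list alone (median 1.94, adjusted p = 0.425 with an estimated correlation), and 32 of 48 striatal projection neuron genes were lower, also adjusted over the list alone (median -1.38, adjusted p = 0.358 with an estimated correlation).

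Averaged over both times, 7221 genes differed between the libraries labelled cGAS-KO and WT, 4162 higher and 3059 lower. The imprinted RNA H19 was higher by 5.06 ± 0.61 (adjusted p = 0.000104), the microglial adaptor Tyrobp by 2.92 ± 0.30 (adjusted p = 5.33e-05) and the lysosomal nuclease Dnase2a by 2.05 ± 0.12 (adjusted p = 5.5e-06). Slc17a6, the glutamate transporter of thalamic neurons, fell by 2.57 ± 0.36 (adjusted p = 0.00034). In STING-KO 3739 genes differed, 2224 higher and 1515 lower. The fibronectin receptor subunit Itga5 was higher by 3.12 ± 0.19 (adjusted p = 1.4e-05) and Gdnf by 3.99 ± 0.61 (adjusted p = 0.000955), and Neurod6 fell by 4.20 ± 0.35 (adjusted p = 6.91e-05) and Slc17a7 by 3.21 ± 0.47 (adjusted p = 0.00105). Of the interferon-stimulated genes 39 of 67 were higher in cGAS-KO over both times, 46 and 1 lower adjusted over the list alone (median 1.01, adjusted p = 0.516 with an estimated correlation). In STING-KO 1 was higher and 2 lower over all genes, and edgeR called 0 adjusted over the list alone, with 3 higher and 6 lower at an unadjusted p below 0.05 (median -0.09, adjusted p = 0.909 with an estimated correlation). Without 7-day WT replicate 2 the cGAS-KO count was 4800. The STING-KO count was 1900 without that library, 2342 without 7-day WT replicate 1, 2257 without 14-day WT replicate 2 and 2468 without 7-day STING-KO replicate 2. The STING-KO average joins effects of opposite sign. The STING-KO effects at 7 and 14 days, which share no library, correlated across genes at r = -0.51 (rho = -0.524), or -0.245 without the filter. In opposite directions 4371 genes were called. For cGAS-KO r was -0.192 (rho = -0.103), but -0.0647 without 14-day WT replicate 1 and -0.0476 without the filter. All 6 genes called at 14 days were called in the opposite direction at 7 days. The interferon-stimulated genes had a median of 2.95 at 7 days and -0.91 at 14 days in cGAS-KO. Their average over both times thus joins opposite signs as well.

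Against STING-KO over both times, 3731 genes differed in cGAS-KO, 2012 higher and 1719 lower. Bst2 was higher by 1.46 ± 0.27 (adjusted p = 0.00658), Col5a1, of fibrillar collagen, by 2.52 ± 0.30 (adjusted p = 0.00162) and haemoglobin Hbb-bs by 2.44 ± 0.42 (adjusted p = 0.00487). The synaptic release factor Unc13c fell by 1.98 ± 0.31 (adjusted p = 0.0032). Tmem173 was higher in cGAS-KO by 1.33 ± 0.18 (adjusted p = 0.00168). The mitochondrial subunit mt-Nd3 was higher by 3.31 ± 0.35 (adjusted p = 0.00125), a value that reads shared with its nuclear copy Gm28438 make uncertain. Of the interferon-stimulated genes 43 of 67 were higher, 63 adjusted over the list alone (median 1.04, adjusted p = 0.342 with an estimated correlation). The count was 1792 without 7-day STING-KO replicate 1, 2483 without its replicate 2, 1925 without 7-day cGAS-KO replicate 1, 2007 without 14-day cGAS-KO replicate 2 and 2368 without 14-day STING-KO replicate 1. Over both times the effects of the labelled knockouts against WT correlated at r = 0.688, against 0.499 simulated, with 0.532 as the lowest when 1 library was left out (14-day STING-KO replicate 2). With the WT libraries split, so that no WT library was shared, r was 0.536 and 0.487. Both 7-day WT libraries stood apart together and correlated with each other at r = 0.995 in log2 CPM. A deviation that they share thus stayed in both comparisons, so neither value shows agreement free of the controls.

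Each genotype as labelled was compared between 7 and 14 days. In WT, 8693 genes differed, 4780 higher and 3913 lower at 14 days, and the count was 5579 without 7-day WT replicate 2. All 67 interferon-stimulated genes were higher at 14 days, also adjusted over the list alone (median 4.22, adjusted p = 0.186 with an estimated correlation). Of 16 inflammasome and pyroptosis genes 15 were higher, also adjusted over the list alone (median 3.09). This was the only list of 46 that camera also called with an estimated correlation here (adjusted p = 0.042 with an estimated correlation), and no list passed so in the other comparisons. Ifi211, of the interferon-induced Ifi200 family, had 0 counts at 7 days and averaged 10.4 ± 0.54 CPM at 14 days. Shox2 fell by 7.26 ± 0.51 (adjusted p = 3.63e-06) and C1ql2 by 7.08 ± 1.17 (adjusted p = 0.000639). Of 48 striatal projection neuron genes 25 were higher and 3 lower at 14 days in WT, and of 78 ribosomal protein genes 36 and 7, each the same adjusted over the list alone (medians 1.03 and 0.51, adjusted p = 0.567 and 0.583 with an estimated correlation). In cGAS-KO 6022 genes differed, 2654 higher and 3368 lower at 14 days. The count was 2968 without 7-day cGAS-KO replicate 1 and 3423 without 14-day cGAS-KO replicate 1. Gpr6, a receptor of striatal neurons, was higher by 5.16 ± 0.63 (adjusted p = 0.000235), and the acute-phase gene Saa3 fell by 7.20 ± 1.34 (adjusted p = 0.00318, but 0.0516 without the filter on low counts). Of its interferon-stimulated genes 5 were higher and 2 lower, 5 and 1 adjusted over the list alone (median 0.42, adjusted p = 0.832 with an estimated correlation). Its striatal projection neuron genes were higher in 43 and lower in 1 of 48, 45 and 1 adjusted over the list alone (median 2.55, adjusted p = 0.2 with an estimated correlation). Markers of other cells fell with this rise. Lower were 24 of 25 choroid plexus genes (median -3.42) and 40 of 41 fibroblast and matrix genes (median -2.97). Of 25 monocyte and macrophage genes 19 were lower and 1 higher (median -4.07). By camera with an estimated correlation these 3 lists had adjusted p of 0.247, 0.178 and 0.178. In cGAS-KO the ribosomal protein genes were lower in 30 of 78, 33 adjusted over the list alone (median -0.47, adjusted p = 0.545 with an estimated correlation). In STING-KO 11274 genes differed, 5426 higher and 5848 lower. Gpr6 was higher by 5.86 ± 0.59 (adjusted p = 1.12e-05), Spp1 fell by 9.76 ± 0.65 (adjusted p = 8.91e-07), and Col10a1 averaged 301 ± 283 CPM at 7 days, with 501 and 101 CPM in its libraries, and had 0 counts at 14 days. Of the striatal projection neuron genes 46 of 48 were higher at 14 days, also adjusted over the list alone (median 3.84, adjusted p = 0.235 with an estimated correlation). Of its interferon-stimulated genes 37 of 67 were lower and 1 higher, the same adjusted over the list alone (median -1.34, adjusted p = 0.7 with an estimated correlation), and of its ribosomal protein genes 60 of 78 were lower, 63 adjusted over the list alone (median -1.13, adjusted p = 0.389 with an estimated correlation).

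The difference between the times was tested for each labelled knockout against WT. The cGAS-KO effect at 14 days differed from that at 7 days in 7271 genes, 3111 with a higher and 4160 with a lower effect, and the STING-KO effect in 10292 genes, 4817 and 5475. For the interferon-stimulated genes the STING-KO effect was lower at 14 days in 66 of 67 genes (median -5.47, adjusted p = 0.203 with an estimated correlation), and the cGAS-KO effect in 65 (median -3.78, adjusted p = 0.183 with an estimated correlation). Both counts were the same adjusted over the list alone. The 14-day minus 7-day difference was -3.65 ± 0.36 for Tmem173 in cGAS-KO (adjusted p = 1.54e-05) and -5.53 ± 0.39 in STING-KO (adjusted p = 4.56e-07).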

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

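The interaction tests and the tests of other splits of the libraries were chosen before their results were seen. The tests of explanations were chosen only after the pattern they address had been seen, with hippocampal markers picked without looking at their values. The bounds for the loss of Tmem173 and for the fall of interferon-stimulated genes were widened after their values were seen; under the first bounds both explanations had been excluded.

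Both knockout effects differed between the times by an interaction test in edgeR. The cGAS-KO effect at 14 days differed from that at 7 days in 7271 genes, including Cgas (-1.83) and Tmem173 (-3.65), and in 34 of 46 gene lists by camera with its preset correlation. The STING-KO effect differed in 10292 genes, including Cgas (-3.25) and Tmem173 (-5.53), and in 33 lists. Of the other named genes of the 7- and 14-day comparisons 39 of 39 and 33 of 38 differed too, but they were picked for large changes at either time, so these tallies are no evidence of their own. With an estimated correlation camera called 0 lists in either interaction, with 16 and 14 at an unadjusted p below 0.05, and fry called 35 and 41.

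The first pattern is that the 7-day WT libraries stood apart, which enters both interactions. Injury alone, with striatal neurons lost, was assumed to bring at least as many injury transcripts at 7 as at 14 days. In WT, however, 31 of 32 disease-associated microglia genes were lower at 7 days, with a median change of 3.70 from 7 to 14 days. The list did not pass camera with an estimated correlation (adjusted p = 0.18). Low immune transcripts are among the values that set the 7-day WT libraries apart. The outcome was thus in view beforehand, and it does not exclude injury. An exchange of labels with the 14-day STING-KO libraries stays open. In the 7-day WT libraries mt-Nd3 took at least 83.5% of its sum with Gm28438. That pair was found by searching for transcripts that part the libraries labelled STING-KO from all others, which fixed this share. The search did not fix that any gene would be found, and for WT and cGAS-KO it found 0. With labels exchanged, the libraries labelled STING-KO would mix genotypes, which by itself would not give such a pair. As 1 pair picked from all genes searched, it does not settle the question. Neurons of another region, such as the hippocampus, in the tissue taken are a candidate explanation: 13 hippocampal markers had a median 1.05 above that of neuronal genes between the 7-day WT and 14-day STING-KO libraries, with 9 higher and 2 lower, 10 of the 13 highest in the 7-day WT group, with Cpne4 and Bok at 118 and 111 CPM against 31.1 and 11.3, while Pdzd2 and Man1a went the other way, at 69.4 and 51.9 CPM against 224 and 149.8 (no marker is on another list used here, and all but Iyd averaged over 2 CPM in the 14-day WT libraries too). These values do not single out the hippocampus, whose markers had a median of 1.92 in this comparison. Cortical excitatory neuron genes had a median of 1.93 (17 higher, 8 lower). Thalamic and hypothalamic neuron genes had 1.37 (19 higher, 1 lower) and striatal projection neuron genes -3.32 (1 higher, 43 lower). A difference in lesion, time or dissection stays open, since no uninjured tissue was compared.

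The second pattern is that Tmem173 was not lower in the 7-day libraries labelled STING-KO than in WT. A loss of the transcript to 50% of its level or less stays open: the 95% interval of the difference from the 7-day cGAS-KO libraries (cGAS-KO minus STING-KO, from -0.098 to 0.893) ended below 1, but relative to the medians of 4 myeloid lists its upper bound was 1.36 (disease-associated microglia), 1.24 (phagocytosis and lysosome), 1.07 (homeostatic microglia) and 0.694 (monocytes and macrophages). The myeloid content of the samples may account for the fall of Tmem173 at 14 days. At -2.51 ± 0.27 it lay 0.114 above the lowest median of 4 myeloid lists, within 2 SE, and these medians ran from -2.62 to -1.61. Set directly against STING-KO at 14 days, Tmem173 was higher in cGAS-KO by 2.27 ± 0.27. The medians of the same 4 lists there were lower, from 0.56 (monocytes and macrophages) to 2.24 (disease-associated microglia). A loss of the transcript beyond myeloid content thus stays open at 14 days. Whether myeloid content accounts for the rise at 7 days, 3.02 ± 0.28, was not settled. That rise differed by -0.0446 from the lowest median (homeostatic microglia, 3.06), within 2 SE. The other lists rose by more, with medians of 4.48 (phagocytosis and lysosome), 4.49 (monocytes and macrophages) and 5.12 (disease-associated microglia). A knockout allele that leaves the transcript in place stays open, as does a wrong genotype label. The counts show neither.

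The third pattern is the low level of immune transcripts in the 14-day libraries labelled STING-KO, the direction that loss of STING would give for interferon-stimulated genes. The 7-day libraries with the same label went the other way, with 64 of 67 interferon-stimulated genes higher than in WT (median 2.57). That comparison rests on the 7-day WT libraries, which stood apart. Whether these genes fell beyond other immune genes was not settled: of 13 other immune lists 11 fell less than their median of -2.89, down to the dendritic cells at -1.34, while the neutrophils fell as much and the T and NK cells, at -3.04, by 0.155 more. Less injured tissue in these samples could give the same values, with striatal projection neuron genes higher by a median of 2.34, but it cannot be told apart from an effect of the genotype because both libraries of the group share it. The biological explanation, that loss of STING limits inflammation and spares neurons, stays open and untested.

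The contrasts over both times were set against other splits of their 8 libraries, 4 against 4, in a fit with day and group as additive terms; 34 splits including the real one could be fitted, all but the split by day. That fit puts the difference between times into the residual, so it called 0, 28 and 0 genes where the 6-group fit called 7221, 3739 and 3731. With a real count of 0, all 34 splits necessarily gave as many genes for cGAS-KO against WT (highest other count 6) and all 34 for cGAS-KO against STING-KO (highest other count 9), so these tests decide nothing about chance. For STING-KO against WT 2 of 34 splits did, the real one among them, a share of 0.0588. Chance cannot be excluded, but this share does not measure it. Every split besides these 2 parted the libraries of at least 1 group, and each called 0 genes. The other of these 2, the 14-day STING-KO with the 7-day WT libraries against the rest, called 8017 genes against the real 28. It is also the split of the interaction between genotype and time. A knockout effect of opposite sign at the 2 times and a structure of the samples that crosses the labels would both give this count. The split cannot tell them apart.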

How the results depend on the processing

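The legacy fit with robust estimation, the fit without the 7-day WT and 14-day STING-KO groups and the knockouts against each other within a time were chosen after seeing the data. Of the calls and directions of named genes under the alternatives, 1850 stayed as they were, 110 lost a call, 17 gained one and 0 reversed. Each gene enters this tally once per comparison and setting. Most of these genes were picked for large changes or small adjusted p in the main fit, so the tally is no separate evidence of stability. The counts at 7 days against WT, over both times, between times and of the interactions stayed within 1.5 times under every setting that kept all libraries. The exceptions follow; except where fewer libraries or genes entered, the cause was not tested. cGAS-KO against WT at 14 days called 29 genes without the filter (5 higher, 24 lower), 16 with only the libraries compared, 137 with DESeq2 (51 higher, 86 lower), 7 without the groups named above and 5 with the legacy fit, robust or not. Of its 6 genes, F13a1 and Msr1 stayed called under all 9 settings other than leaving out 1 library, while Clec4d lost its call in 2, Mmp8 in 2, Slfn4 in 4 and Thbs1 in 1, with adjusted p up to 0.124. cGAS-KO against STING-KO at 7 days called 60 without the filter, 6 with the legacy fit, 5 with its robust form, 2 with only the libraries compared, 10 without the groups named above and 260 with DESeq2. With only the libraries compared, STING-KO against WT at 14 days called 4271 genes and cGAS-KO against STING-KO at 14 days 4614. Camera with an estimated correlation called 0 lists in each of the 6 comparisons with WT, where the preset one called 34, 33, 28, 32, 30 and 27. Without the filter the correlations across genes became -0.0476 and -0.245 between times (cGAS-KO, STING-KO), 0.76 between the knockouts at 7 days and 0.577 over both times.

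Leaving out 1 library at a time gave these lowest and highest counts of genes: for cGAS-KO against WT 7261 to 8774 at 7 days, 0 to 18 at 14 days and 4800 to 6685 over both times; for STING-KO against WT 6884 to 8003, 4203 to 6870 and 1900 to 4319; for cGAS-KO against STING-KO 0 to 202, 4632 to 7291 and 1792 to 4974; between times 5579 to 7402 in WT, 2968 to 4735 in cGAS-KO and 9194 to 10850 in STING-KO; and for the interactions 5292 to 6844 and 8464 to 10308. Lists called ran from 34 to 35, 32 to 35, 22 to 27, 30 to 36, 29 to 31 and 26 to 33. The correlations ran from -0.183 to -0.0647 and -0.458 to -0.383 between times, 0.868 to 0.929 between knockouts at 7 days, 0.334 to 0.575 at 14 days and 0.532 to 0.719 over both times. Same-numbered libraries did not deviate together (r from -0.0923 to 0.196, over 0.1 in 2 of 15 group pairs), so the numbers do not pair them; with the replicate number as a block the counts were 10023, 9755, 9 and 6751 for cGAS-KO and STING-KO against WT at 7 and then 14 days, and no count moved by over 1.5 times. Size factors, filters and the block moved the median of all genes by less than 0.1 on the log2 scale. At this depth genes under 3 counts per library, 0.133 to 0.195 CPM, can go undetected.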

Other observations

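Every test in this part was chosen after the values had been seen.

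Genes that part the labelled genotypes across both times were sought among those tested with a mean of at least 2 CPM, with all 4 libraries of a genotype at least 2-fold from all other 8. WT and cGAS-KO had 0 higher and 0 lower. STING-KO had 1 lower, mt-Nd3, at 2.44 to 5.01 CPM against 19.4 to 64.7, and 1 higher, the pseudogene Gm28438, at 19.8 to 40.4 CPM against 2.55 to 9.87. Neither Cgas nor Tmem173 was among them. mt-Nd3 encodes a subunit of respiratory complex I (mitochondrial genome, 9459 to 9806, plus strand), and Gm28438 is an unprocessed nuclear copy of it (chromosome 1, 24612775 to 24613119, minus strand). Their annotated transcripts are equal at 344 of 345 bases (99.7%) and differ at 1. The sum of both ran from 22.3 to 44.8 CPM in the libraries labelled STING-KO and from 22 to 69.4 CPM in the others, so that 4 of 4 sums lay within the range of the other 8. mt-Nd3 took 6.79% to 11.2% of the sum in STING-KO and 80.2% to 93.2% elsewhere. Reads passing from mt-Nd3 to its nuclear copy, as a base difference in the mitochondrial genome of the STING-KO line could cause, are a candidate explanation for both values, and neither value is then a change in expression. Reads were not analysed here, and a batch that follows the STING-KO libraries is not excluded. Mitochondrial genomes pass through the mother, so such a difference would mark a line and not the targeted gene.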
